A study of Mus musculus with 12 samples.

How the data were processed

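RNA was measured in keratinocytes isolated enzymatically from mouse back skin and sorted by cell surface antigens, with no culture and no treatment, per the labels' protocols. RNA was extracted with a column kit, amplified linearly by in vitro transcription and labelled with biotin, per the labels' protocols. The values used are log2 expression values per probe set, as deposited by the authors. GCOS, GCRMA and Partek are named in the submitters' processing notes, with no statement of what each was used for or in which order. That the scale is log2 was read from the values, which ran from 1.68 to 14.7 over 12 arrays and 45101 probe sets. The scanner files were not used here, so background correction and normalization are the authors' own. The difference between the 3' and 5' control probe sets was 1.50 to 2.32 log2 units for Actb and 1.34 to 1.98 for Gapdh, with the lowest of both on bulge replicate 1. No array was a copy of another: the smallest mean absolute difference between 2 arrays was 0.21 log2 units.

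Gene names came from the platform's annotation table, with symbols updated through the gene ID in a reference gene table of assembly GRCm38.p6, which was used for names only. Of the 45101 probe sets, 34958 had 1 symbol (34754 of them matched by gene ID), 932 had several and 9211 are unnamed here. The 64 control probe sets were left out. Each gene was represented by the probe set with the highest mean over all arrays, which gave 18193 genes. A gene was tested if its log2 value was at least 4 in at least 4 arrays, which left 15320 genes and set 2873 aside as dim. A group mean under log2 4 was treated as near the background, and a fold against it is given as a bound computed against log2 4.

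Groups were taken from the labels, and the fit, the filter, the thresholds, the gene lists and the rule for naming genes were set before the data were examined. Group means of all 12 arrays were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with no covariate), and the 3 differences between groups were tested with a two-sided test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, over the genes tested. Gene lists were tested with limma's camera, with a preset correlation of 0.01 between genes and adjustment over 36 lists, and again with an estimated correlation. On simulated data with 100 genes changed by 1 and 100 by 2 log2 units among 15320, the fit of bulge against germ called 75% and 94% of them in the right direction, with 11 false calls among 180. For bulge against epidermis it called 77% and 97%, with 12 false calls among 186.

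The genes named were chosen by a fixed rule: per comparison the 10 largest and 10 smallest differences among called genes whose groups did not overlap, up to 4 called members of each list with the largest differences, the genes of the sorting antigens, and per group the 10 genes with the largest smaller-of-2 differences. Of 263 genes that met the rule, 184 are named, and the others, among them genes whose call ended in an alternative, were left out after the results were seen. Dbp, Per3, Uty and Xist are named beyond the rule. The 38 lists hold the genes of the sorting antigens, Y-linked genes, and bulge stem cell genes, hair germ and matrix progenitor genes, basal keratinocyte and hemidesmosome genes, epidermal differentiation genes, upper follicle genes, sebaceous gland genes, inner bulge and companion layer keratins, hair shaft and inner root sheath genes, melanocyte genes, Langerhans and myeloid cell genes, T cell genes, fibroblast genes, dermal papilla genes, endothelial genes, smooth muscle and pericyte genes, Schwann cell genes, Merkel cell genes, DNA replication genes, mitosis genes, cyclin-dependent kinase inhibitor and quiescence genes, Wnt feedback target genes, secreted Wnt antagonist genes, BMP and TGF-beta pathway genes, hedgehog pathway genes, Notch pathway genes, FGF pathway genes, Eph receptor and ephrin genes, basement membrane and matrix genes, MHC class I presentation genes, interferon response genes, wound and barrier activation genes, immediate early genes, cholesterol synthesis genes, glycolysis genes, prostaglandin genes and circadian clock genes. The number of arrays, 4 per group, limits which differences can be called. Members were chosen from textbook knowledge, so a list's name says which genes it holds and not which cells were in a sample.

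The series text says that 4 pools of 3 mice were each sorted into the 3 populations, so arrays with the same replicate number were taken to come from the same pool. Deviations from the group means correlated across genes between arrays of the same number at r = 0.117 to 0.469 for bulge and germ, 0.274 to 0.437 for germ and epidermis, and -0.0497 to 0.324 for bulge and epidermis. Each array correlated best with its own number in 4, 4 and 2 of 4 cases. The alternatives tried were no filter and a stricter filter on dim probe sets, quantile normalization, median centring, the mean of a gene's probe sets, every probe set on its own, eBayes with trend and robust settings, array weights, the replicate number as a block, the 2 groups compared alone, an adjusted p threshold of 0.01, a fold minimum of 2, and leaving out each array in turn. Fits on replicates 1 and 2 alone, on replicates 3 and 4 alone, and with the block but without bulge replicate 1 were added after the data were seen. For the correlation of the differences against epidermis, unchanged groups were simulated, epidermis included. The real epidermis arrays were also divided between the 2 comparisons. Genomic positions are not given, because the values come with no genome build.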

Results

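Gene expression was measured in keratinocytes sorted from the back skin of mice aged 50 days, whose hair follicles were in telogen, the resting phase of the hair cycle. Sorting on surface antigens gave 3 populations. Cells positive for CD34, CD200 and CD49 were taken as bulge, the niche in the outer root sheath that holds slow-cycling follicle stem cells. Cells negative for CD34 and positive for CD200 and CD49 were taken as secondary hair germ, the cell cluster below the bulge from which the lower follicle regrows. Cells positive for CD49 alone were taken as interfollicular epidermis. Each group held 4 replicates, each replicate was a pool of 3 mice, and every sorted sample was hybridised to 1 of 12 arrays, so the 4 pools per group limit the precision. Levels are given as mean log2 value ± SD over the 4 pools of a group, folds come from differences of those means, SE is the standard error of the log2 difference, and adjusted p is limma's after Benjamini-Hochberg adjustment. The median log2 value over all probe sets was 6.2 to 6.35 on 11 arrays and 6.89 on bulge replicate 1. Arrays of 1 group correlated across probe sets at 0.99 to 0.995, and bulge replicate 1 correlated with the other bulge arrays at 0.973 to 0.978. The mice are labelled female, yet the Y-linked genes Eif2s3y, Kdm5d and Uty averaged 10.52, 8.29 and 6.18 on the 6 arrays of replicates 1 and 2 and 3.06, 3.12 and 2.72 on the 6 arrays of replicates 3 and 4. Xist, transcribed from the inactive X chromosome, averaged 12.28 and 12.49 on the same arrays. Each group holds both kinds of pool in equal number, and the 3 Y-linked genes tested differed between no groups (0 called by limma, and 0 at an unadjusted p under 0.05).

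**Figure D1:**
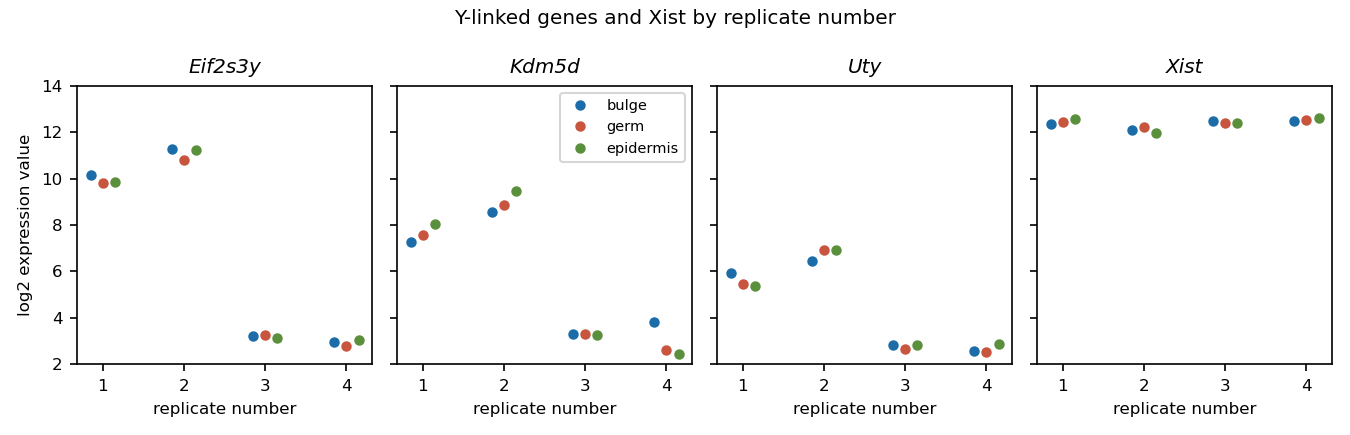
Log2 expression values of 3 Y-linked genes and Xist on each array against replicate number, with 1 point per array coloured by group. Eif2s3y lies between 9.83 and 11.26 on the arrays of replicates 1 and 2 and between 2.77 and 3.26 on those of replicates 3 and 4, while Xist stays between 11.98 and 12.62.

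The transcripts of the antigens used for sorting check the labels and are no finding between the groups. Cd34 stood at 12.67 ± 0.48 in bulge, 8.66 ± 1.35 in germ and 7.94 ± 0.87 in epidermis. It was 16.1-fold higher in bulge than in germ (SE 0.60, adjusted p = 0.000398) and 26.5-fold higher than in epidermis (adjusted p = 7.4e-05), and germ and epidermis did not pass the test against each other (adjusted p = 0.465). Cd200 stood at 12.18 ± 0.19 in bulge, 11.94 ± 0.11 in germ and 8.61 ± 0.65 in epidermis, and was 11.9-fold higher in bulge and 10.1-fold higher in germ than in epidermis (adjusted p = 7.03e-07 and 3.89e-06). The labels do not say which member of the CD49 family, the integrin alpha chains, was stained. Itga6, the chain carried by basal keratinocytes, was at 12.36 ± 0.22, 12.27 ± 0.04 and 12.86 ± 0.09, and was 1.41-fold lower in bulge and 1.5-fold lower in germ than in epidermis (adjusted p = 0.00451 and 0.00201). Between bulge and germ, Cd200 and Itga6 did not pass the test (adjusted p = 0.538 and 0.583). The other integrin alpha genes on the list, Itga1, Itga2, Itga3, Itga4 and Itga5, averaged 9.16, 6.56, 11.29, 9.32 and 9.75 in bulge, 7.87, 5.44, 10.54, 6.77 and 7.89 in germ and 7.54, 6.93, 12.06, 4.76 and 8.69 in epidermis.

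**Figure D2:**
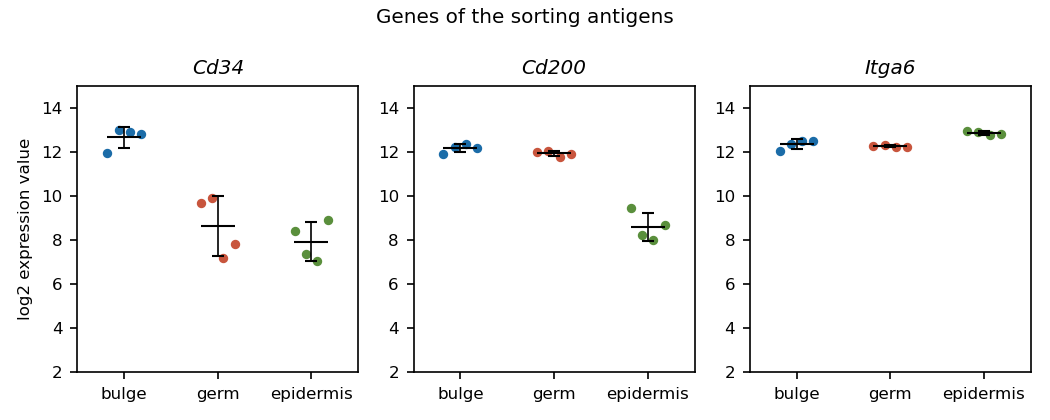
Log2 expression values of the genes of the sorting antigens on each array by group, with 1 point per pool and bars for the mean ± SD of 4 pools. Cd34 averages 12.67 in bulge and 8.66 in germ, and Cd200 averages 11.94 in germ and 8.61 in epidermis.

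The comparison of bulge with germ sets the CD34-positive against the CD34-negative cells among those positive for CD200 and CD49. The kinase-anchoring protein gene Sphkap (42.1-fold, SE 0.40), the secreted angiopoietin-like gene Angptl7 (25.6-fold, SE 0.39), choline acetyltransferase Chat (25-fold, SE 0.28), the urea transporter gene Slc14a1 (23.9-fold, SE 0.34), the GDNF co-receptor gene Gfra1 (19-fold, SE 0.32) and the protease inhibitor gene Spink2 (17.5-fold, SE 0.17) were higher in bulge (adjusted p = 1.11e-07 to 7.8e-06). Sphkap stood at 10.98 ± 0.32 in bulge and 5.58 ± 0.62 in germ, and Chat at 8.84 ± 0.20 and 4.19 ± 0.72. Slc22a22, Pdzrn4, Fam171b and Sorbs2 were also among the 10 largest, at 28.7-fold, 25.6-fold, 21.7-fold and at least 17-fold, the last as a bound because germ lay under log2 4. The ceramide hydroxylase gene Degs2 (15.9-fold, SE 0.24), the epithelial ETS factor gene Elf5 (10.6-fold, SE 0.38), the keratin gene Krt4 (10.4-fold, SE 0.29), the kallikrein gene Klk6 (8.27-fold, SE 0.22) and Slc46a2 (8.32-fold, SE 0.15) were higher in germ (adjusted p = 4.51e-07 to 4.25e-05). Degs2 stood at 5.97 ± 0.25 in bulge and 9.96 ± 0.43 in germ. The cornified envelope precursor genes Sprr2f and Sprr2h were also among the 10 largest, at 10.4-fold and 8.94-fold.

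Bulge stem cell genes had 19 higher and 0 lower of 23 tested, 19 adjusted over the list alone, in bulge against germ (camera adjusted p = 4.08e-09, and adjusted p = 0.356 with an estimated correlation). The endocytic adaptor gene Dab2 (15.9-fold, SE 0.24), the growth factor gene Fgf18 (15.6-fold, SE 0.28), Ltbp2 (11.8-fold, SE 0.43) and Dkk3 (7.54-fold, SE 0.24) were higher in bulge (adjusted p = 1.04e-06 to 8.28e-05). BMP and TGF-beta pathway genes had 15 higher and 2 lower of 24 tested, 18 adjusted over the list alone (camera adjusted p = 0.000942, and adjusted p = 0.474 with an estimated correlation). The BMP antagonist gene Grem1 (9.53-fold, SE 0.34), the ligand gene Bmp6 (4.35-fold, SE 0.30) and the BMP-responsive gene Id3 (2.86-fold, SE 0.28) were higher in bulge (adjusted p = 2.66e-05 to 0.00148). Hedgehog pathway genes had 8 higher and 0 lower of 12 tested, 8 adjusted over the list alone (camera adjusted p = 0.000942, and adjusted p = 0.43 with an estimated correlation). The co-receptor gene Cdon (3.12-fold, SE 0.16) and the transcription factor gene Gli2 (2.73-fold, SE 0.37) were higher in bulge (adjusted p = 2.01e-05 to 0.012). Basement membrane and matrix genes had 13 higher and 2 lower of 23 tested, 18 adjusted over the list alone (camera adjusted p = 0.00207, and adjusted p = 0.462 with an estimated correlation). Egfl6 (12.6-fold, SE 0.43), Tnc (5.29-fold, SE 0.21), Col18a1 (4.12-fold, SE 0.16) and Col7a1 (3.41-fold, SE 0.16) were higher in bulge (adjusted p = 4.94e-06 to 6.22e-05). Basal keratinocyte and hemidesmosome genes had 8 higher and 0 lower of 10 tested, 8 adjusted over the list alone (camera adjusted p = 0.000752, and adjusted p = 0.118 with an estimated correlation). The laminin chain gene Lamb3 (2.75-fold, SE 0.13), the integrin gene Itgb4 (2.45-fold, SE 0.10) and the hemidesmosomal collagen gene Col17a1 (1.88-fold, SE 0.09) were higher in bulge (adjusted p = 6.02e-06 to 1.39e-05).

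Epidermal differentiation genes went the other way, with 0 higher and 16 lower of 23 tested, 17 adjusted over the list alone (camera adjusted p = 8.29e-10, and adjusted p = 0.163 with an estimated correlation). The involucrin gene Ivl (5.27-fold, SE 0.26), the barrier transcription factor gene Grhl3 (4.84-fold, SE 0.19) and the cornifelin gene Cnfn (4.47-fold, SE 0.33) were higher in germ (adjusted p = 7.83e-06 to 0.000402). Upper follicle genes had 1 higher and 6 lower of 9 tested, 8 adjusted over the list alone (camera adjusted p = 0.000358, and adjusted p = 0.43 with an estimated correlation). Gata6 (3.44-fold, SE 0.20), Krt79 (2.79-fold, SE 0.27) and Cst6 (2.38-fold, SE 0.15) were higher in germ (adjusted p = 5.4e-05 to 0.00129). Sebaceous gland genes had 0 higher and 10 lower of 11 tested, 10 adjusted over the list alone (camera adjusted p = 2.09e-05, and adjusted p = 0.462 with an estimated correlation). The fatty acid elongase gene Elovl3 (4.42-fold, SE 0.41), the lipid droplet gene Cidea (4.25-fold, SE 0.53) and the nuclear receptor gene Pparg (3.51-fold, SE 0.42) were higher in germ (adjusted p = 0.00181 to 0.0111). Cholesterol synthesis genes had 0 higher and 11 lower of 15 tested, 13 adjusted over the list alone (camera adjusted p = 5.86e-07, and adjusted p = 0.43 with an estimated correlation). Mvd (2.72-fold, SE 0.25) and Sqle (2.06-fold, SE 0.17) were higher in germ (adjusted p = 0.000742 to 0.000959). Wound and barrier activation genes had 0 higher and 12 lower of 14 tested, 12 adjusted over the list alone (camera adjusted p = 7.96e-09, and adjusted p = 0.157 with an estimated correlation). The calprotectin subunit gene S100a9 (6.53-fold, SE 0.54), Sprr1b (4.99-fold, SE 0.20) and the defensin gene Defb3 (5.27-fold, SE 0.48) were higher in germ (adjusted p = 9.53e-06 to 0.00278).

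No member of the mitosis genes was called between bulge and germ, with 21 tested, 0 called adjusted over the list alone, 1 at limma's unadjusted p under 0.05 and adjusted p = 0.0609 for the list. Without bulge replicate 1, 7 of them were called lower in bulge. The mitosis list passed as lower in bulge with median centring (adjusted p = 0.0141), with no filter on dim probe sets (0.0345), with quantile normalization (0.0381), without bulge replicate 1 (0.000765), without germ replicate 1 (0.0376) or without germ replicate 4 (0.0482). DNA replication genes had 0 higher and 1 lower of 18 tested, 0 adjusted over the list alone (adjusted p = 0.316) and glycolysis genes 0 higher and 0 lower of 12 tested, 0 adjusted over the list alone and 2 at limma's unadjusted p under 0.05 (adjusted p = 0.248). MHC class I presentation genes had 0 higher and 1 lower of 11 tested, 1 adjusted over the list alone (adjusted p = 0.0537). The MHC list passed as lower in bulge with median centring (adjusted p = 0.0461), with no filter on dim probe sets (0.0314), without bulge replicate 1 (0.0349), without epidermis replicate 1 (0.0499), without germ replicate 1 (0.0452) or without germ replicate 4 (0.0432). Hair germ and matrix progenitor genes had 4 higher and 3 lower of 16 tested, 8 adjusted over the list alone (adjusted p = 0.938). Edar (3.87-fold, SE 0.39) and Ovol1 (3.36-fold, SE 0.34) were higher in germ (adjusted p = 0.00201 to 0.00273). Hoxc13 went the other way, with values of 10.25 to 10.64 in bulge and 8.47 to 9.28 in germ. Of the 16 genes on this list, 1 was called higher in germ than in both other groups, and 3 were called higher in bulge than in both. Secreted Wnt antagonist genes had 3 higher and 3 lower of 11 tested, 6 adjusted over the list alone (adjusted p = 0.938). Sfrp1 (3.67-fold, SE 0.16) was higher in bulge (adjusted p = 8.21e-06). Dkk2 (at least 2.21-fold, SE 0.24) was higher in germ (adjusted p = 0.000138). Eph receptor and ephrin genes had 8 higher and 1 lower of 17 tested, 9 adjusted over the list alone (adjusted p = 0.221), and melanocyte genes 1 higher and 1 lower of 11 tested, 2 adjusted over the list alone (adjusted p = 0.907). Fibroblast genes had 5 higher and 2 lower of 11 tested, 8 adjusted over the list alone (adjusted p = 0.779). The fibroblast list passed as higher in bulge with the stricter filter on dim probe sets (adjusted p = 0.0463). Langerhans and myeloid cell genes had 1 higher and 0 lower of 13 tested, 1 adjusted over the list alone (adjusted p = 0.221). The Langerhans list passed as lower in bulge with the replicate number as a block (adjusted p = 0.017) or without bulge replicate 1 (0.0145). In all, 4365 of 15320 genes were called between bulge and germ, 2795 higher and 1570 lower in bulge, and 1788 of them differed by at least 2-fold. All 4 values of 1 group lay above the 4 of the other for 29.2% of genes, where chance gives 2.86%. Median centring of each array, which shifted the median difference of all genes by -0.16 log2 units, gave 2108 genes higher and 2486 lower, so that 45.9% of the calls were higher against 64% on the values as deposited. Without bulge replicate 1, 5395 genes were called, 2831 higher and 2564 lower. Member counts of lists that then moved by over 1.5 times, to or from at least 3 genes, were, as higher and lower, 1 and 5 for Langerhans and myeloid cell genes, 0 and 4 for T cell genes, 0 and 7 for mitosis genes, 3 and 4 for cyclin-dependent kinase inhibitor and quiescence genes, 3 and 3 for Wnt feedback target genes, 12 and 4 for basement membrane and matrix genes, 0 and 3 for MHC class I presentation genes, 2 and 3 for interferon response genes and 1 and 3 for glycolysis genes.

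**Figure D3:**
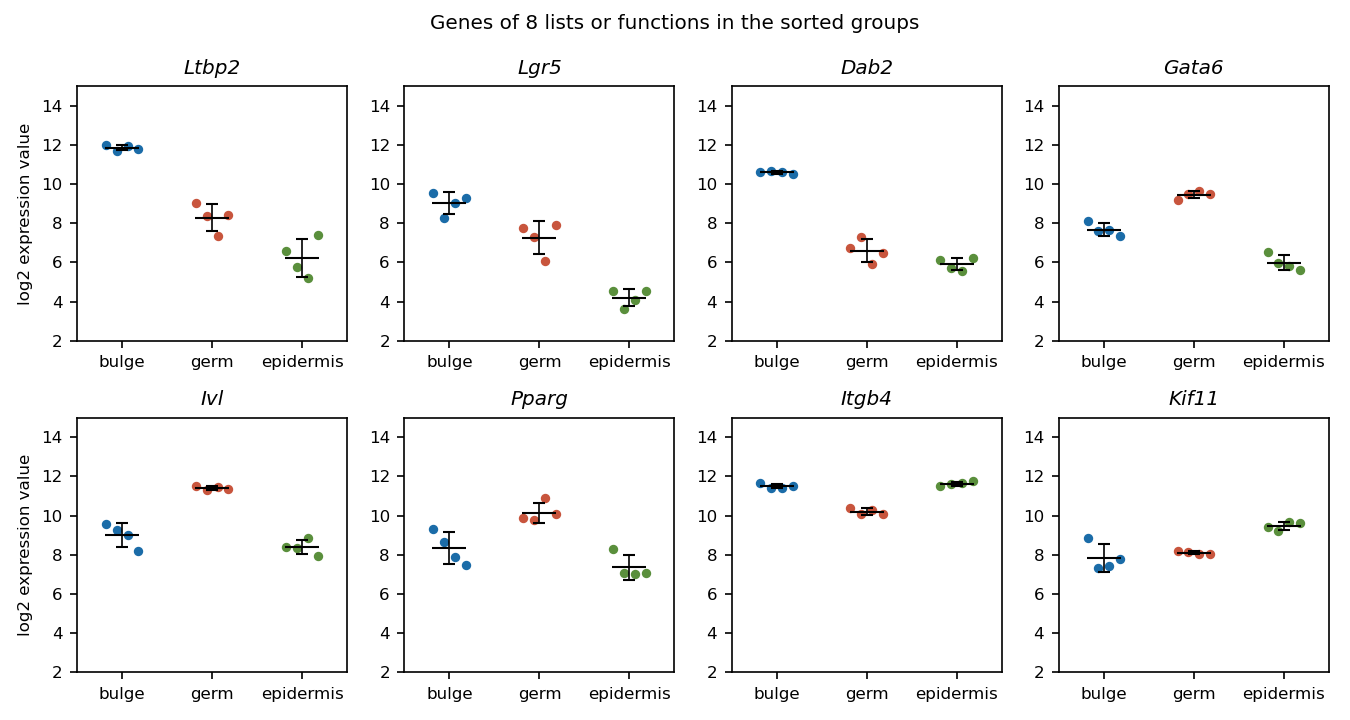
Log2 expression values of 8 genes on each array by group, with 1 point per pool and bars for the mean ± SD of 4 pools. Ltbp2 falls from 11.86 in bulge to 8.29 in germ and 6.24 in epidermis, Gata6, Ivl and Pparg are highest in germ, Itgb4 is lowest in germ, and Kif11 averages 9.48 in epidermis against 7.85 and 8.10 in bulge and germ.

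The comparison of bulge with epidermis sets the cells positive for CD34 and CD200 against those negative for both. The calmodulin-dependent kinase gene Camk4 (70.6-fold, SE 0.35), Grem1 (60.2-fold, SE 0.34), Tmtc1 (55.6-fold, SE 0.34), Gfra1 (54.5-fold, SE 0.32), the collagen gene Col5a2 (53.6-fold, SE 0.33) and the matrix proteoglycan gene Aspn (53.4-fold, SE 0.41) were higher in bulge (adjusted p = 1.48e-07 to 7.28e-07). Grem1 stood at 11.49 ± 0.20 in bulge and 5.58 ± 0.54 in epidermis. Sphkap, Col8a2, Hoxd8 and Minar2 were also among the 10 largest, at 59.7-fold, 51.3-fold, 50.9-fold and at least 48.7-fold. The leukotriene receptor gene Cysltr1 (18.6-fold, SE 0.29), the cytokine receptor gene Il20ra (17.9-fold, SE 0.35), the G protein subunit gene Gna14 (17.4-fold, SE 0.20), the ligand gene Bmp4 (15.5-fold, SE 0.38), the transcription factor gene Irf4 (13.7-fold, SE 0.31) and the hyaluronan synthase gene Has3 (13.1-fold, SE 0.37) were higher in epidermis (adjusted p = 8.62e-08 to 9.86e-06). Bmp4 stood at 6.51 ± 0.92 in bulge and 10.46 ± 0.29 in epidermis. Apol7a, Crispld2, Gsdmc2 and Sox6 were also among the 10 largest, at 15.2-fold, 15.1-fold, 14.2-fold and 13.4-fold higher in epidermis.

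Bulge stem cell genes had 20 higher and 0 lower of 23 tested, 21 adjusted over the list alone in bulge against epidermis (camera adjusted p = 1.49e-14, and adjusted p = 0.423 with an estimated correlation). Ltbp2 (49.2-fold, SE 0.43), the R-spondin receptor gene Lgr5 (28.7-fold, SE 0.40), the Wnt inhibitor gene Wif1 (at least 29.1-fold, SE 0.43) and Dab2 (25.8-fold, SE 0.24) were higher in bulge (adjusted p = 1.06e-07 to 2.07e-06). Hedgehog pathway genes had 7 higher and 1 lower of 12 tested, 8 adjusted over the list alone (camera adjusted p = 0.00188, and adjusted p = 0.423 with an estimated correlation). Gli2 (22.3-fold, SE 0.37), Gli1 (18.2-fold, SE 0.43) and Hhip (4.93-fold, SE 0.26) were higher in bulge (adjusted p = 2.42e-06 to 2.96e-05). BMP and TGF-beta pathway genes had 15 higher and 3 lower of 24 tested, 21 adjusted over the list alone (camera adjusted p = 0.000555, and adjusted p = 0.423 with an estimated correlation). Bmp6 (10.4-fold, SE 0.30) was higher in bulge (adjusted p = 3.6e-06). The list also holds Grem1, higher in bulge, and Bmp4, higher in epidermis. Eph receptor and ephrin genes had 9 higher and 1 lower of 17 tested, 11 adjusted over the list alone (camera adjusted p = 0.00434, and adjusted p = 0.423 with an estimated correlation). Ephb1 (7.06-fold, SE 0.51), Efna3 (2.86-fold, SE 0.13) and Efna5 (2.11-fold, SE 0.12) were higher in bulge (adjusted p = 2.19e-06 to 0.00109). Upper follicle genes had 7 higher and 0 lower of 9 tested, 8 adjusted over the list alone (camera adjusted p = 0.000245, and adjusted p = 0.423 with an estimated correlation). Prdm1 (3.97-fold, SE 0.35), Gata6 (3.19-fold, SE 0.20), Cst6 (2.83-fold, SE 0.15) and Krt79 (2.82-fold, SE 0.27) were higher in bulge (adjusted p = 1.01e-05 to 0.000914). Fibroblast genes had 6 higher and 0 lower of 11 tested, 6 adjusted over the list alone (camera adjusted p = 0.00526, and adjusted p = 0.447 with an estimated correlation). Col1a2 (24.1-fold, SE 0.56), Fbln1 (6.58-fold, SE 0.41), Col1a1 (5.14-fold, SE 0.37) and Col6a1 (3.5-fold, SE 0.26) were higher in bulge (adjusted p = 4.78e-05 to 0.000345).

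All 21 mitosis genes tested were lower in bulge than in epidermis, 21 adjusted over the list alone (camera adjusted p = 8.32e-13, and adjusted p = 0.423 with an estimated correlation). The spindle motor gene Kif11 (3.09-fold, SE 0.28), the checkpoint kinase gene Bub1 (2.89-fold, SE 0.26), the ubiquitin-conjugating enzyme gene Ube2c (2.85-fold, SE 0.20) and the spindle protein gene Nusap1 (2.71-fold, SE 0.20) were higher in epidermis (adjusted p = 0.000109 to 0.000729). DNA replication genes had 0 higher and 9 lower of 18 tested, 11 adjusted over the list alone (camera adjusted p = 2.39e-05, and adjusted p = 0.423 with an estimated correlation). Mcm3 (2.22-fold, SE 0.23) and Mcm2 (1.9-fold, SE 0.15) were higher in epidermis (adjusted p = 0.000389 to 0.00204). Glycolysis genes had 1 higher and 10 lower of 12 tested, 12 adjusted over the list alone (camera adjusted p = 0.000179, and adjusted p = 0.423 with an estimated correlation). Pgk1 (1.49-fold, SE 0.09) and Tpi1 (1.5-fold, SE 0.12) were higher in epidermis (adjusted p = 0.000436 to 0.00228). MHC class I presentation genes had 0 higher and 5 lower of 11 tested, 7 adjusted over the list alone (camera adjusted p = 0.0111, and adjusted p = 0.423 with an estimated correlation). The peptide-trimming protease gene Erap1 (1.68-fold, SE 0.17) and the transactivator gene Nlrc5 (1.39-fold, SE 0.10) were higher in epidermis (adjusted p = 0.00299 to 0.00463). Wound and barrier activation genes had 0 higher and 6 lower of 14 tested, 8 adjusted over the list alone (camera adjusted p = 0.0101, and adjusted p = 0.423 with an estimated correlation). The cytokine genes Il33 (7.71-fold, SE 0.33) and Il1b (7.14-fold, SE 0.28) were higher in epidermis (adjusted p = 9.23e-06 to 2.31e-05). The wound list call ended with median centring (adjusted p = 0.0544).

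Hair germ and matrix progenitor genes had 7 higher and 4 lower of 16 tested, 11 adjusted over the list alone in bulge against epidermis (adjusted p = 0.27). Hoxc13 (22.5-fold, SE 0.25), Lef1 (8.11-fold, SE 0.30) and Trps1 (5.95-fold, SE 0.20) were higher in bulge (adjusted p = 1.53e-07 to 8.26e-06). Epidermal differentiation genes had 3 higher and 5 lower of 23 tested, 8 adjusted over the list alone (adjusted p = 0.813). Calml3 (10.2-fold, SE 0.27) was higher in bulge (adjusted p = 1.61e-06). Tgm3 (6.62-fold, SE 0.36) was higher in epidermis (adjusted p = 9.31e-05). The median and mean difference of this list were above 0 (0.21 and 0.07) while camera ranked it below other genes. Basal keratinocyte and hemidesmosome genes had 0 higher and 1 lower of 10 tested, 1 adjusted over the list alone (adjusted p = 0.508). Krt14 (1.27-fold, SE 0.08) was higher in epidermis (adjusted p = 0.00632). Cholesterol synthesis genes had 0 higher and 0 lower of 15 tested, 0 adjusted over the list alone and 3 at limma's unadjusted p under 0.05 (adjusted p = 0.583). Basement membrane and matrix genes had 7 higher and 2 lower of 23 tested, 10 adjusted over the list alone (adjusted p = 0.0575). Col4a2 (6.24-fold, SE 0.25) and Col4a1 (4.47-fold, SE 0.29) were higher in bulge (adjusted p = 6.86e-06 to 0.000115). The matrix list passed as higher in bulge with median centring (adjusted p = 0.0259), with no filter on dim probe sets (0.0326), with quantile normalization (0.0302), with the replicate number as a block (0.043), without bulge replicate 3 (0.0394), without epidermis replicate 2 (0.0286), without germ replicate 1 (0.0485) or without germ replicate 3 (0.0289). Secreted Wnt antagonist genes had 5 higher and 1 lower of 11 tested, 6 adjusted over the list alone (adjusted p = 0.0575). Dkk3 (6.09-fold, SE 0.24) was higher in bulge (adjusted p = 5.93e-06). The Wnt antagonist list passed as higher in bulge with median centring (adjusted p = 0.028), with no filter on dim probe sets (0.0442), without bulge replicate 4 (0.0428), without epidermis replicate 1 (0.0403) or without germ replicate 3 (0.0322). Melanocyte genes had 3 higher and 0 lower of 11 tested, 2 adjusted over the list alone (adjusted p = 0.0835). Mitf (4.88-fold, SE 0.11) was higher in bulge (adjusted p = 4.94e-08). The melanocyte list passed as higher in bulge with median centring (adjusted p = 0.0195), with the replicate number as a block (0.0148), without bulge replicate 3 (0.0323), without bulge replicate 4 (0.0365) or without epidermis replicate 2 (0.0305). Sebaceous gland genes had 3 higher and 0 lower of 11 tested, 3 adjusted over the list alone (adjusted p = 0.164). Dgat2 (2.28-fold, SE 0.23) was higher in bulge (adjusted p = 0.00187). The sebaceous list passed as higher in bulge without bulge replicate 4 (adjusted p = 0.0442) or without epidermis replicate 1 (0.00804). Langerhans and myeloid cell genes had 1 higher and 0 lower of 13 tested, 1 adjusted over the list alone (adjusted p = 0.813). Mfge8 (10.4-fold, SE 0.24) was higher in bulge (adjusted p = 7.05e-07). In all, 4669 genes were called between bulge and epidermis, 2827 higher and 1842 lower in bulge, and 2112 differed by at least 2-fold. The groups did not overlap for 29.6% of genes. Median centring of each array, which shifted the median difference of all genes by -0.23 log2 units, gave 2103 genes higher and 4189 lower, so that 33.4% of the calls were higher against 60.5% on the values as deposited. Without bulge replicate 1, 5983 genes were called, 2880 higher and 3103 lower. Member counts of lists that then moved by over 1.5 times, to or from at least 3 genes, were, as higher and lower, 0 and 16 for DNA replication genes, 17 and 6 for BMP and TGF-beta pathway genes and 2 and 3 for interferon response genes.

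The comparison of germ with epidermis sets CD200-positive against CD200-negative cells among those negative for CD34. Degs2 (24-fold, SE 0.24), the matrix protein gene Abi3bp (19.6-fold, SE 0.46), Gdpd1 (19-fold, SE 0.22), the monocarboxylate transporter gene Slc5a8 (18.4-fold, SE 0.21), the EGF receptor ligand gene, Btc (17.8-fold, SE 0.26) and Calhm5 (17.6-fold, SE 0.30) were higher in germ (adjusted p = 2.72e-07 to 3.78e-05). Degs2 stood at 9.96 ± 0.43 in germ and 5.37 ± 0.39 in epidermis, and Btc at 8.65 ± 0.30 and 4.49 ± 0.32. Cldn10 and Slc26a7 were at least 21-fold and at least 13.9-fold higher, as bounds because epidermis lay under log2 4. The actin-bundling protein gene Pls1 (9.38-fold, SE 0.32), Cysltr1 (9.37-fold, SE 0.29), Meiob (9.31-fold, SE 0.29), the neurotrophic factor gene Gdnf (7.91-fold, SE 0.20), Zmat4 (7.79-fold, SE 0.36) and the BMP receptor gene Bmpr1b (7.62-fold, SE 0.26) were higher in epidermis (adjusted p = 1.5e-06 to 0.000104). The collagenase gene Mmp13 was at least 5.94-fold higher in epidermis, with germ under log2 4.

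Epidermal differentiation genes had 16 higher and 1 lower of 23 tested, 20 adjusted over the list alone in germ against epidermis (camera adjusted p = 8.57e-10, and adjusted p = 0.176 with an estimated correlation). Ivl (8.12-fold, SE 0.26), Calml3 (7.91-fold, SE 0.27), Cdsn (5.66-fold, SE 0.36) and Cnfn (5.52-fold, SE 0.33) were higher in germ (adjusted p = 9.21e-06 to 0.000301). Upper follicle genes had 8 higher and 0 lower of 9 tested, 9 adjusted over the list alone (camera adjusted p = 1.04e-08, and adjusted p = 0.176 with an estimated correlation). Gata6 (11-fold, SE 0.20), Krt79 (7.85-fold, SE 0.27), Cst6 (6.74-fold, SE 0.15) and Prdm1 (5.56-fold, SE 0.35) were higher in germ (adjusted p = 4.48e-07 to 0.000274). Sebaceous gland genes had 10 higher and 0 lower of 11 tested, 10 adjusted over the list alone (camera adjusted p = 1.03e-07, and adjusted p = 0.335 with an estimated correlation). Cidea (7.27-fold, SE 0.53), Pparg (6.9-fold, SE 0.42), Elovl3 (6.29-fold, SE 0.41) and Dgat2 (6.12-fold, SE 0.23) were higher in germ (adjusted p = 1.13e-05 to 0.00187). Cholesterol synthesis genes had 13 higher and 0 lower of 15 tested, 13 adjusted over the list alone (camera adjusted p = 9.35e-08, and adjusted p = 0.335 with an estimated correlation). Mvd (4.32-fold, SE 0.25), Lss (2.66-fold, SE 0.24) and Sqle (2.65-fold, SE 0.17) were higher in germ (adjusted p = 7.48e-05 to 0.00108). Bulge stem cell genes had 12 higher and 3 lower of 23 tested, 17 adjusted over the list alone (camera adjusted p = 1.55e-05, and adjusted p = 0.335 with an estimated correlation). Wif1 (at least 10.4-fold, SE 0.43), Foxc1 (11.9-fold, SE 0.26), Lgr5 (8.37-fold, SE 0.40) and Tbx1 (5.06-fold, SE 0.39) were higher in germ (adjusted p = 3.29e-06 to 0.000968). Hair germ and matrix progenitor genes had 8 higher and 2 lower of 16 tested, 11 adjusted over the list alone (camera adjusted p = 0.0141, and adjusted p = 0.335 with an estimated correlation). Hoxc13 (8.56-fold, SE 0.25), Lef1 (8.31-fold, SE 0.30), Gli1 (6.81-fold, SE 0.43) and Edar (4.46-fold, SE 0.39) were higher in germ (adjusted p = 6.17e-06 to 0.00161). In bulge, Hoxc13 and Gli1 were higher still, and Lef1 (9.38 to 10.16) overlapped with germ (8.90 to 10.17).

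All 21 mitosis genes tested were lower in germ than in epidermis, 21 adjusted over the list alone (camera adjusted p = 2.7e-11, and adjusted p = 0.335 with an estimated correlation). Kif11 (2.6-fold, SE 0.28), the mitotic cyclin gene Ccnb2 (2.58-fold, SE 0.24), the centromere protein gene Cenpf (2.51-fold, SE 0.17) and Ube2c (2.43-fold, SE 0.20) were higher in epidermis (adjusted p = 0.000147 to 0.002999). DNA replication genes had 0 higher and 9 lower of 18 tested, 13 adjusted over the list alone (camera adjusted p = 4.24e-05, and adjusted p = 0.335 with an estimated correlation). The G1/S cyclin gene Ccne2 (1.66-fold, SE 0.16) was higher in epidermis (adjusted p = 0.00638). Basal keratinocyte and hemidesmosome genes had 0 higher and 7 lower of 10 tested, 8 adjusted over the list alone (camera adjusted p = 3.06e-06, and adjusted p = 0.0191 with an estimated correlation). Itgb4 (2.67-fold, SE 0.10), Lamb3 (2.36-fold, SE 0.13) and Col17a1 (1.86-fold, SE 0.09) were higher in epidermis (adjusted p = 3.29e-06 to 3.51e-05). This was the list call that also passed with an estimated correlation. Glycolysis genes had 0 higher and 10 lower of 12 tested, 11 adjusted over the list alone (camera adjusted p = 0.00117, and adjusted p = 0.335 with an estimated correlation). Pkm (1.44-fold, SE 0.09) and Pfkp (1.4-fold, SE 0.11) were higher in epidermis (adjusted p = 0.00132 to 0.00743).

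Wound and barrier activation genes had 6 higher and 3 lower of 14 tested, 9 adjusted over the list alone in germ against epidermis (camera adjusted p = 0.0237, and adjusted p = 0.428 with an estimated correlation). The lipocalin gene Lcn2 (9.35-fold, SE 0.42), Sprr1a (4.3-fold, SE 0.25), Sprr1b (4.14-fold, SE 0.20) and Defb3 (4.2-fold, SE 0.48) were higher in germ (adjusted p = 2.22e-05 to 0.00796). The wound list call ended without bulge replicate 1 (adjusted p = 0.0675) or without epidermis replicate 2 (0.0528). BMP and TGF-beta pathway genes had 9 higher and 5 lower of 24 tested, 19 adjusted over the list alone (camera adjusted p = 0.0237, and adjusted p = 0.578 with an estimated correlation). Grem1 (6.32-fold, SE 0.34) and Tgfb3 (5.27-fold, SE 0.31) were higher in germ (adjusted p = 0.000123 to 0.000148). Bmp4 (6.8-fold, SE 0.38) was higher in epidermis (adjusted p = 0.000231). The BMP list call ended without bulge replicate 1 (adjusted p = 0.0675) or without germ replicate 2 (0.0506). Secreted Wnt antagonist genes had 5 higher and 1 lower of 11 tested, 6 adjusted over the list alone (camera adjusted p = 0.0145, and adjusted p = 0.335 with an estimated correlation). Sfrp2 (3.15-fold, SE 0.27) and Notum (1.92-fold, SE 0.16) were higher in germ (adjusted p = 0.000715 to 0.00122). The Wnt antagonist list call ended with the stricter filter on dim probe sets (adjusted p = 0.106). Eph receptor and ephrin genes had 4 higher and 0 lower of 17 tested, 4 adjusted over the list alone (camera adjusted p = 0.0275, and adjusted p = 0.335 with an estimated correlation). Efna3 (1.88-fold, SE 0.13) and Ephb6 (1.54-fold, SE 0.09) were higher in germ (adjusted p = 0.000222 to 0.000447). The Eph list call ended with the replicate number as a block (adjusted p = 0.0516), without epidermis replicate 1 (0.0551) or without germ replicate 2 (0.05001). Fibroblast genes had 7 higher and 2 lower of 11 tested, 10 adjusted over the list alone (camera adjusted p = 0.0123, and adjusted p = 0.428 with an estimated correlation). Col6a3 (at least 3.02-fold, SE 0.33), Col1a2 (4.92-fold, SE 0.56) and Dpt (at least 2.41-fold, SE 0.27) were higher in germ (adjusted p = 0.000155 to 0.00965). The fibroblast list call ended with the stricter filter on dim probe sets (adjusted p = 0.564). Melanocyte genes had 2 higher and 0 lower of 11 tested, 2 adjusted over the list alone (camera adjusted p = 0.00636, and adjusted p = 0.507 with an estimated correlation). Kit (at least 5.2-fold, SE 0.49) and Mitf (2.47-fold, SE 0.11) were higher in germ (adjusted p = 6.17e-06 to 0.00107). Langerhans and myeloid cell genes had 2 higher and 0 lower of 13 tested, 1 adjusted over the list alone (camera adjusted p = 0.0275, and adjusted p = 0.643 with an estimated correlation). The secreted phagocytosis protein gene Mfge8 (2.56-fold, SE 0.24) was higher in germ (adjusted p = 0.00137). The Langerhans list call ended without epidermis replicate 2 (adjusted p = 0.069), without epidermis replicate 3 (0.0601) or without germ replicate 1 (0.127). Hedgehog pathway genes had 4 higher and 3 lower of 12 tested, 8 adjusted over the list alone (adjusted p = 0.271). Gli2 (8.16-fold, SE 0.37) was higher in germ (adjusted p = 0.000105). Smo (1.8-fold, SE 0.09) was higher in epidermis (adjusted p = 4.08e-05). Basement membrane and matrix genes had 6 higher and 9 lower of 23 tested, 17 adjusted over the list alone (adjusted p = 0.345). Fras1 (3.4-fold, SE 0.32) and Frem1 (3.19-fold, SE 0.31) were higher in germ (adjusted p = 0.00156 to 0.00189). Tnc (4.13-fold, SE 0.21) was higher in epidermis (adjusted p = 2.94e-05). The median and mean of the matrix list were -0.30 and 0.05. MHC class I presentation genes had 0 higher and 1 lower of 11 tested, 0 adjusted over the list alone (adjusted p = 0.345). In all, 3563 genes were called between germ and epidermis, 1845 higher and 1718 lower in germ, and 1650 differed by at least 2-fold. The groups did not overlap for 33.8% of genes. Median centring of each array, which shifted the median difference of all genes by -0.07 log2 units, gave 1793 genes higher and 2587 lower, so that 40.9% of the calls were higher against 51.8% on the values as deposited. Without bulge replicate 1, 5125 genes were called, 2387 higher and 2738 lower. No bulge array enters the means of germ and epidermis, so this change comes from the estimate of the spread that the 3 groups share. Member counts of lists that then moved by over 1.5 times, to or from at least 3 genes, were, as higher and lower, 9 and 4 for hair germ and matrix progenitor genes, 5 and 1 for hair shaft and inner root sheath genes, 5 and 0 for melanocyte genes, 4 and 0 for Langerhans and myeloid cell genes, 0 and 15 for DNA replication genes and 5 and 4 for cyclin-dependent kinase inhibitor and quiescence genes.

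**Figure D4:**
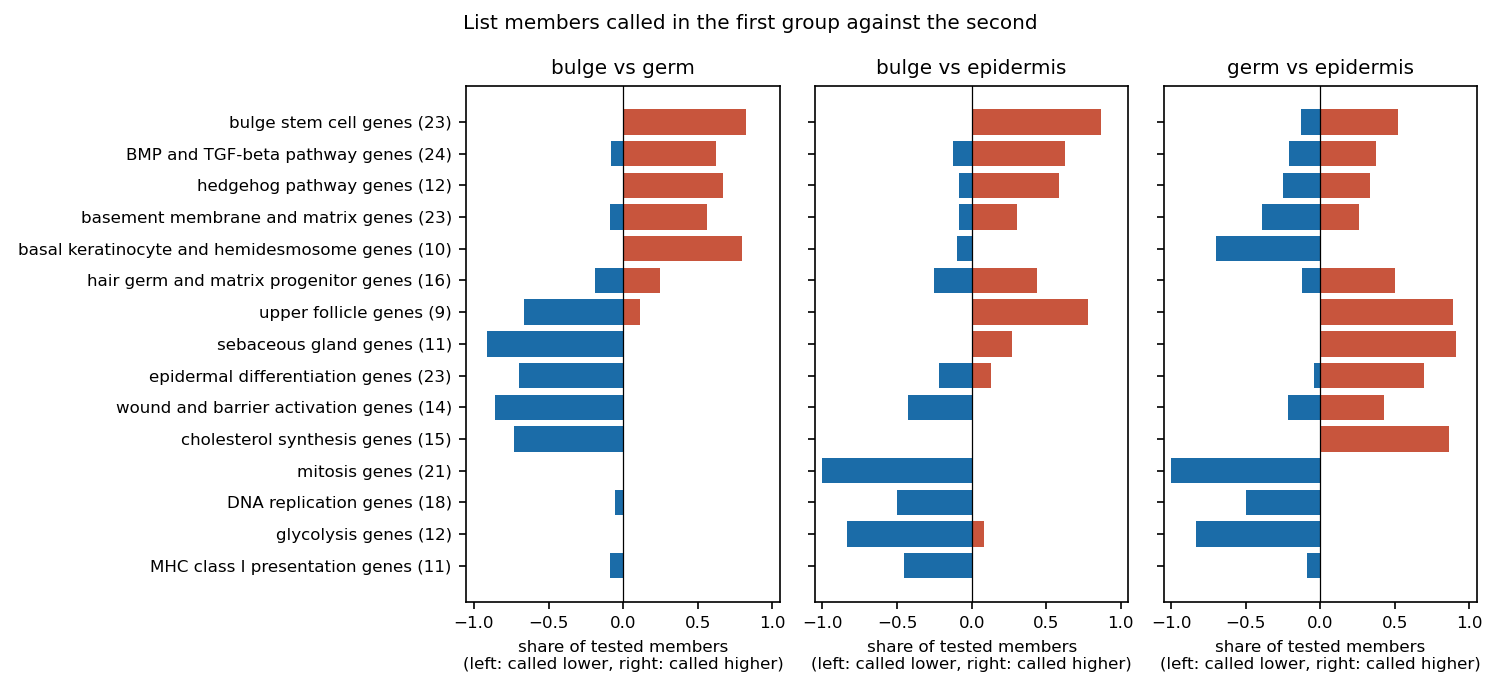
Share of the tested members of 15 gene lists called lower (left of 0) or called higher (right of 0) in the first group of each comparison, with the number tested in brackets and 1 panel per comparison. All 21 mitosis genes are called lower in bulge and in germ than in epidermis. Most tested genes of the upper follicle, sebaceous gland and epidermal differentiation lists are called higher in germ than in bulge and than in epidermis.

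Genes called higher in 1 group than in both others numbered 1849 for bulge, 798 for germ and 942 for epidermis, of which 774, 440 and 364 exceeded both by at least 2-fold. The count for epidermis was 1583 without bulge replicate 1 and 1695 with median centring. By the smaller of the 2 differences, bulge was led by Sphkap, Slc22a22, Angptl7, Pdzrn4 and Chat, at least 25-fold above both other groups. Germ was led by Degs2, Elf5, Fam3b (8.36 ± 0.23), Slc46a2 and Klk6, 8.27-fold or more above both. Epidermis was led by Pls1 (7.56 ± 0.19), Cysltr1 (8.31 ± 0.33), Meiob (8.77 ± 0.22), Bmpr1b and Crispld2, at 9.38-fold to 7.1-fold above the nearer group. Mmp13 and Vcam1, which come before Bmpr1b without the floor of log2 4, are known only as at least 5.94-fold and at least 6.22-fold higher, since bulge and germ lay under it, and another probe set of Vcam1 did not pass the test between germ and epidermis (adjusted p = 0.396). Genes lower in 1 group than in both others numbered 643 for bulge, 550 for germ and 1035 for epidermis.

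The differences of bulge and of germ against epidermis correlated across the 15320 genes tested at r = 0.635, where genes are not independent replicates and both comparisons use the same 4 epidermis arrays. In 50 simulations of unchanged groups, epidermis included, the correlation was 0.503 on average (0.449 to 0.548). With the epidermis arrays divided 2 and 2 the observed value was 0.536 to 0.645. The covariance was 0.405 against 0.0254 simulated, a difference of 0.379. The 2 differences had the same sign for a share of 0.675 of genes, against 0.666 simulated (0.659 to 0.674), and with the epidermis arrays divided 2 and 2, so that no array is shared, the share was 0.599 to 0.653. Called genes shared by both comparisons numbered 1035 higher in both follicle groups than in epidermis and 942 lower in both. Independent lists of these sizes give 340 and 207, which leaves the shared arrays out of account, and the simulated unchanged groups gave 0 and 0.04, since they have few calls at all, so neither is a full expectation. Opposite calls numbered 113 and 53. Among the genes higher in both were Lgr5, Wif1, Gli1, Gli2, Hoxc13 and Lef1, and among those lower in both Bmp4, Cysltr1, the Wnt ligand gene Wnt5a and the surface antigen gene Thy1, the last 2 by 10.6-fold and 7.78-fold in bulge.

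The remaining lists passed camera's test in no comparison. Their counts are members called higher and lower in the first group, for bulge against germ, bulge against epidermis and germ against epidermis in that order, with the adjusted p of the list in the same order. Inner bulge and companion layer keratins (4 tested) had 0 and 2, 1 and 1, and 2 and 0, with 3, 3 and 2 adjusted over the list alone (adjusted p = 0.278, 0.813 and 0.107). Hair shaft and inner root sheath genes (18 tested) had 2 and 0, 5 and 1, and 1 and 1, with 1, 6 and 1 adjusted over the list alone (adjusted p = 0.745, 0.813 and 0.433). T cell genes (11 tested) had 0 and 1, 0 and 1, and 0 and 1, with 1, 1 and 1 adjusted over the list alone (adjusted p = 0.221, 0.446 and 0.737). Dermal papilla genes (11 tested) had 3 and 3, 3 and 3, and 2 and 3, with 7, 7 and 6 adjusted over the list alone (adjusted p = 0.71, 0.626 and 0.757). Endothelial genes (11 tested) had 1 and 1, 3 and 0, and 3 and 1, with 4, 4 and 4 adjusted over the list alone (adjusted p = 0.635, 0.27 and 0.271). Smooth muscle and pericyte genes (11 tested) had 2 and 0, 4 and 1, and 3 and 1, with 2, 5 and 4 adjusted over the list alone (adjusted p = 0.779, 0.626 and 0.345). Schwann cell genes (4 tested) had 1 and 0, 0 and 2, and 0 and 2, with 1, 2 and 2 adjusted over the list alone (adjusted p = 0.938, 0.0835 and 0.0868). Merkel cell genes (8 tested) had 3 and 0, 3 and 0, and 1 and 0, with 3, 3 and 1 adjusted over the list alone (adjusted p = 0.278, 0.0876 and 0.208). The T cell list, between bulge and germ, passed as lower in bulge without bulge replicate 1 (adjusted p = 0.0145). The Schwann cell list, between germ and epidermis, passed as lower in germ without epidermis replicate 4 (adjusted p = 0.0498). The endothelial list, between germ and epidermis, passed as higher in germ with the stricter filter on dim probe sets (adjusted p = 0.0145). The Merkel cell list, between bulge and epidermis, passed as higher in bulge with the stricter filter on dim probe sets (adjusted p = 0.025).

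Cyclin-dependent kinase inhibitor and quiescence genes (13 tested) had 1 and 1, 3 and 1, and 4 and 2, with 2, 4 and 7 adjusted over the list alone (adjusted p = 0.635, 0.814 and 0.345). Wnt feedback target genes (11 tested) had 3 and 0, 4 and 1, and 3 and 3, with 4, 5 and 7 adjusted over the list alone (adjusted p = 0.987, 0.593 and 0.195). Notch pathway genes (14 tested) had 3 and 3, 2 and 4, and 3 and 3, with 6, 6 and 6 adjusted over the list alone (adjusted p = 0.291, 0.464 and 0.754). FGF pathway genes (15 tested) had 6 and 1, 4 and 2, and 4 and 4, with 8, 7 and 8 adjusted over the list alone (adjusted p = 0.291, 0.278 and 0.345). Interferon response genes (12 tested) had 2 and 1, 2 and 1, and 1 and 1, with 3, 3 and 2 adjusted over the list alone (adjusted p = 0.987, 0.766 and 0.641). Immediate early genes (15 tested) had 0 and 1, 2 and 0, and 2 and 0, with 0, 2 and 2 adjusted over the list alone (adjusted p = 0.779, 0.814 and 0.562). Prostaglandin genes (10 tested) had 2 and 3, 0 and 3, and 1 and 4, with 7, 7 and 6 adjusted over the list alone (adjusted p = 0.677, 0.0876 and 0.0765). Circadian clock genes (17 tested) had 6 and 1, 5 and 3, and 1 and 2, with 7, 8 and 3 adjusted over the list alone (adjusted p = 0.316, 0.626 and 0.6003). The prostaglandin list, between germ and epidermis, passed as lower in germ with the stricter filter on dim probe sets (adjusted p = 0.0455). Median, mean and test differed in sign, with no call, for hair germ and matrix progenitor genes, hair shaft and inner root sheath genes, melanocyte genes, smooth muscle and pericyte genes, Schwann cell genes, cyclin-dependent kinase inhibitor and quiescence genes, Wnt feedback target genes, secreted Wnt antagonist genes, immediate early genes and prostaglandin genes between bulge and germ. They also differed for epidermal differentiation genes, inner bulge and companion layer keratins, hair shaft and inner root sheath genes, T cell genes, smooth muscle and pericyte genes, Wnt feedback target genes and interferon response genes between bulge and epidermis, and for smooth muscle and pericyte genes, cyclin-dependent kinase inhibitor and quiescence genes, basement membrane and matrix genes and immediate early genes between germ and epidermis.

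The levels of Abi3bp, Aspn, Cck, Cldn10, Col17a1, Col1a2, Crispld2, Dbp, Efna4, Fbln1, Fgfr1, Grem1, Hoxd8, Il1b, Itga5, Itgb4, Kit, Krt14, Krt8, Lama3, Lamb3, Lcn2, Lss, Mcm2, Mcm3, Mfge8, Minar2, Mvd, Mx1, Notch3, Notum, Pecam1, Pfkl, Pparg, Smo, Sox10, Sprr2h, Tbx1, Tpi1, Wif1 and Xist come from probe sets that can also match other transcripts.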

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

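The tests of cross-hybridisation and normalization for the Y-linked genes, of distribution, shared pool, list members and lowered genes for bulge replicate 1, and of a mixture for the germ genes were chosen only after the result was seen. In 567 groups of 4 arrays, the array medians and 188 named genes were searched for an array whose gap to the others takes up most of the group's range, and 29 were found where chance alone, at about 1 in 20 groups, gives 28.35. Log2 values of these arrays are given with the range of the other 3 of the group. Bulge replicate 1 stood apart for Bmp6 (9.14, others 8.11 to 8.28), Dbp (11.76, others 13.19 to 13.27), Fgfr1 (11.84, others 11.97 to 11.99), Mmp13 (4.18, others 2.69 to 2.8), Mx1 (6.38, others 5.42 to 5.56), Nrarp (10.83, others 10.41 to 10.47) and Usp18 (9.53, others 8.41 to 8.54). Bulge replicate 2 stood apart for Hpgd (12, others 11.4 to 11.44). Bulge replicate 3 stood apart for Gli1 (9.07, others 10.08 to 10.25). Bulge replicate 4 stood apart for Btc (5.33, others 6.34 to 6.45) and Efna5 (11.5, others 11.38 to 11.39). Epidermis replicate 1 stood apart for Cldn10 (4.78, others 3.44 to 3.6), Ephb1 (4.08, others 4.59 to 4.69), Kit (4.08, others 3.27 to 3.38), Mvd (8.94, others 8.05 to 8.18) and Pparg (8.3, others 7 to 7.08). Epidermis replicate 4 stood apart for Bmpr1b (8.35, others 7.64 to 7.7), Hpgd (11.4, others 11.06 to 11.11) and Slc5a8 (3.83, others 4.42 to 4.51). Germ replicate 1 stood apart for Hpgds (7.83, others 8.86 to 9.05) and Pls1 (3.49, others 4.57 to 4.71). Germ replicate 2 stood apart for Lfng (9.54, others 9 to 9.07). Germ replicate 3 stood apart for Hoxc13 (8.47, others 9.22 to 9.28), Krt14 (13.47, others 13.42 to 13.42), Lef1 (8.9, others 10.01 to 10.17), Ovol1 (9.95, others 10.21 to 10.25) and Tgfb3 (8.56, others 9.45 to 9.55). Germ replicate 4 stood apart for Mmp13 (4.8, others 2.98 to 3.16).

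Signal of Y-linked genes was present where the label says female: on replicates 1 and 2, Uty averaged 6.18, Kdm5d 8.29 and Eif2s3y 10.52, against 2.72, 3.12 and 3.06 on replicates 3 and 4. Pools of male mice alone are argued against by Xist, whose mean on replicates 1 and 2 differed from that on replicates 3 and 4 by -0.20 log2 units. Cross-hybridisation with 1 other gene is argued against by all 3 genes exceeding replicates 3 and 4 of their group by over 2 log2 units on 6 of 6 arrays, and a difference in normalization by array medians that differed by 0.0864 log2 units. Pools of replicates 1 and 2 that held mice of both sexes, or labels of sex that do not cover every mouse, stay open and were not tested further. Both kinds of pool fall equally into the 3 groups, and no biological explanation was tested.

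Bulge replicate 1 had an array median of 6.89, against 6.26 to 6.35 on the other bulge arrays, and 2090 genes deviated by over 1 log2 unit, 1667 upward and 423 downward. Its overall distribution as the whole cause is argued against by a mean correlation with the other bulge arrays of 0.9774 after quantile normalization, under the lowest among those arrays (0.9921). A difference of the whole pool as the cause for all genes is argued against by correlations across genes with the deviation of germ and epidermis replicate 1 of at most 0.162, while for immune cells it fits: 22 of 24 Langerhans, myeloid and T cell genes were highest on replicate 1 in germ and 22 in epidermis, where 1 in 4 gives 6. More RNA of immune cells and melanocytes in this array fits for the genes of their 3 lists, of which 82.9% were raised by over 1 log2 unit against 23.9% of other genes at their level. Basal keratinocyte and bulge genes, which a mixture dilutes most, had a median deviation of -0.0569, and 2 of 33 fell by over 1 log2 unit. The 423 genes lowered had a median of -1.50, but they were chosen for deviating by over 1 log2 unit. The deviations were not corrected for the raised median of this array, which could hide a dilution. A mixture as the source of the lowered genes is therefore not decided. The share of the 3 lists among the deviating genes, 1.44%, decides nothing, as it can reach 1.68% at most. RNA quality, amplification and cell number stay open for the other genes, although the 3' minus 5' difference of Actb was the lowest of all arrays (1.5, others 1.9 to 2.32), and no biological explanation was tested.

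Of 43 tested genes on the upper follicle, sebaceous gland and epidermal differentiation lists, 29 were called higher in germ than in both other groups, for example Krt79 at 13.36 ± 0.07 in germ, 11.89 ± 0.26 in bulge and 10.39 ± 0.67 in epidermis. A germ sample mixed from cells of the other 2 populations would lie between them, and is argued against by the share of 0.674 of these genes called above both. Normalization is argued against because at least 27 genes were so called with quantile normalization and with median centring, and bulge replicate 1 because 27 were so called without it. Expression of these genes by hair germ cells, and cells of the upper follicle or sebaceous gland that fall inside the CD34-negative, CD200-positive and CD49-positive gate, stay open as hypotheses, since arrays of pooled cells do not separate them.

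For each comparison the 8 arrays of the 2 groups can be divided into 4 and 4 in 35 ways. Only 1 of these, the real one, gave as many genes called as the 4365 of bulge against germ, where the highest other division gave 1. The same held for the 4669 genes of bulge against epidermis (highest other 2) and the 3563 of germ against epidermis (highest other 0). Every other division mixes the 2 groups, which puts their differences into the spread and leaves few calls. With 35 divisions to compare, the 3 counts do not exclude chance by themselves. Among the 8 divisions that part all 4 pairs of the same number, the highest other than the real one gave 0 genes in each comparison.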

How the results depend on the processing

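The fits on 2 replicates alone, and with the block but without bulge replicate 1, were chosen after seeing the data. Counts of genes called, and of genes higher in 1 group than in both others, stayed within 1.5 times with either filter on dim probe sets, quantile normalization, the mean of a gene's probe sets, every probe set on its own, eBayes with trend and robust settings, the replicate block and replicates 3 and 4 alone, as did the counts of genes called from the 2 groups compared alone. Median centring raised the genes higher in epidermis than in both others to 1695, and array weights gave 5700 genes called between germ and epidermis, 1203 higher in germ than in both and 1763 higher in epidermis than in both (the cause was not tested). The block without bulge replicate 1 gave 5834, 1240 and 1821 for the same 3 counts, and here too the cause was not tested. A fold minimum of 2 left 1788, 2112 and 1650 genes called and 774, 440 and 364 higher in bulge, germ and epidermis than in both others, by its construction. An adjusted p threshold of 0.01 left 2781 genes between bulge and germ, 2283 between germ and epidermis, and 1209, 508 and 551 higher in 1 group than in both others. Replicates 1 and 2 alone gave 704, 1559 and 834 genes called and 404, 119 and 153 higher in 1 group. Replicates 3 and 4 alone, with as many arrays, gave 4671, 5322 and 3717 genes called. The number of arrays therefore does not account for the low counts, and their cause was not tested. With 1 array left out, genes called ranged over 3513 to 5395, 3992 to 5983 and 2871 to 5125, with the highest without bulge replicate 1 in each. Between germ and epidermis this array alters only the shared estimate of the spread, and the 2 groups compared alone gave 4927 genes called. Genes higher in epidermis than in both others ranged over 734 to 1583, the lowest without epidermis replicate 3 and the highest without bulge replicate 1. With an estimated correlation, 0 lists passed between bulge and germ, 0 between bulge and epidermis and 1 between germ and epidermis. A higher correlation between the genes of a list makes camera stricter. The estimates were 0.77 for mitosis genes and 0.341 for bulge stem cell genes, against the preset 0.01. The basal keratinocyte list had -0.0092 and passed between germ and epidermis, but not between bulge and germ (camera adjusted p = 0.118). The correlation alone therefore does not account for every lost call. The correlation of the differences against epidermis averaged 0.593 with the epidermis arrays split 2 and 2, where no array is shared. The replicate block gave 4559, 4848 and 3778 genes called and held 94.6%, 94.8% and 94.8% of the genes called without it. It ended the calls of Efna4 between bulge and germ, Plin2 and Notch3 between bulge and epidermis, and Pecam1 and Mcm3 between germ and epidermis, moved the 4 list calls named with their lists, and changed no other call of a named gene or list. Tested with every probe set on its own, 48 of the 418 differences of named genes kept their sign but lost their call on the least agreeing probe set. Of 418 differences of named genes, 401 of them called, and 108 list results, none that was called changed direction, except that in genes with several probe sets the least agreeing one gave the opposite sign and no call (adjusted p = 0.109 to 0.976). These log2 differences were, between bulge and germ, Lama3 (-0.0703), Casp14 (0.12) and Ngfr (-0.00801), between bulge and epidermis, Sox10 (-0.0484), Mylk (-0.0806), Ngfr (0.0288), Piezo2 (-0.0109), Rrm1 (0.208), Boc (-0.335) and Pfkl (0.02996), and between germ and epidermis, Itga4 (-0.0139), Mylk (-0.0509), Ngfr (0.0368), Piezo2 (-0.178), Rrm1 (0.181) and Pfkl (0.0643), and the cause was not tested. On replicates 1 and 2 alone 176 of the 418 differences of named genes lost their call, and on replicates 3 and 4 alone 31. Both fits have 2 arrays per group, so array number does not account for their difference. List calls ended on replicates 1 and 2 alone, with the list's adjusted p in brackets, were basal keratinocyte and hemidesmosome genes (0.0537) and basement membrane and matrix genes (0.0883) between bulge and germ, with 5 gained: melanocyte genes (0.0047) and Merkel cell genes (0.0457) between bulge and epidermis, inner bulge and companion layer keratins (0.0465), Wnt feedback target genes (0.0311) and hedgehog pathway genes (0.0452) between germ and epidermis. On replicates 3 and 4 alone those ended were wound and barrier activation genes (0.0732) between bulge and epidermis, fibroblast genes (0.0561), secreted Wnt antagonist genes (0.0634), BMP and TGF-beta pathway genes (0.0983), Eph receptor and ephrin genes (0.0983) and wound and barrier activation genes (0.0561) between germ and epidermis, with 5 gained: Langerhans and myeloid cell genes (0.000709), T cell genes (0.0118) and mitosis genes (0.000434) between bulge and germ, melanocyte genes (0.0477) and basement membrane and matrix genes (0.0477) between bulge and epidermis. With the block but without bulge replicate 1 that of BMP and TGF-beta pathway genes (0.0548) between germ and epidermis ended, and 8 were gained: Langerhans and myeloid cell genes (0.00401), T cell genes (0.00622), mitosis genes (0.00116), MHC class I presentation genes (0.0112) and circadian clock genes (0.0149) between bulge and germ, melanocyte genes (0.0469) and basement membrane and matrix genes (0.0369) between bulge and epidermis, inner bulge and companion layer keratins (0.0358) between germ and epidermis.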

Other observations

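Of the tests here, those of the clock genes and of a share that differed between pools were chosen only after the result was seen. Lists without a list call hold members that went different ways, of which some are given. The growth factor gene Fgf1 (5.23-fold, SE 0.22), the FGF receptor gene Fgfr1 (2.87-fold, SE 0.15) and the FGF-responsive transcription factor gene Etv5 (2.41-fold, SE 0.23) were higher in bulge than in germ (adjusted p = 1.15e-05 to 0.00155). Fgf1 (5.66-fold, SE 0.22) and Fgfr1 (2.99-fold, SE 0.15) were higher in germ than in epidermis (adjusted p = 9.47e-06 to 1.98e-05). The FGF receptor gene Fgfr3 (2.33-fold, SE 0.13) was higher in epidermis than in germ (adjusted p = 3.51e-05). The FGF pathway inhibitor gene Spry4 (2.69-fold, SE 0.16) was higher in bulge than in epidermis (adjusted p = 2.48e-05). The receptor gene Notch3 (3.97-fold, SE 0.27) and the Notch-responsive gene Nrarp (2.51-fold, SE 0.14) were higher in germ than in bulge (adjusted p = 3.06e-05 to 0.000211). Nrarp (2.58-fold, SE 0.14) was higher in germ than in epidermis (adjusted p = 2.83e-05). The Notch-modifying enzyme gene Lfng (2.16-fold, SE 0.14) and the Notch target gene Hey1 (2.34-fold, SE 0.37) were higher in bulge than in germ (adjusted p = 9.57e-05 to 0.0269). The call of Hey1 ended without bulge replicate 1 (adjusted p = 0.0537) and with 4 other arrays left out in turn, and another probe set of Lfng did not pass the test (adjusted p = 0.253). The peptide hormone gene Cck (8.48-fold, SE 0.33) and the simple epithelial keratin gene Krt8 (2.54-fold, SE 0.32) were higher in bulge than in germ (adjusted p = 3.03e-05 to 0.00794). The myosin light chain gene Myl9 (5.44-fold, SE 0.28) and the proteoglycan gene Cspg4 (4.37-fold, SE 0.17) were higher in bulge than in germ (adjusted p = 5.28e-06 to 6.11e-05). Myl9 (12.6-fold, SE 0.28) and Cspg4 (12.1-fold, SE 0.17) were higher in bulge than in epidermis (adjusted p = 5.04e-08 to 1.39e-06).

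Enzymes of prostaglandin metabolism went different ways. The cyclooxygenase gene Ptgs2 (2.42-fold, SE 0.20) and the prostaglandin-degrading enzyme gene Hpgd (2.61-fold, SE 0.17) were higher in bulge than in germ (adjusted p = 7.87e-05 to 0.000473). Ptgs2 (3.53-fold, SE 0.20) and Hpgd (1.98-fold, SE 0.17) were higher in epidermis than in germ (adjusted p = 4.18e-05 to 0.000991). The prostaglandin D synthase gene Hpgds (3.33-fold, SE 0.30) and the prostaglandin E synthase gene Ptges (1.43-fold, SE 0.13) were higher in germ than in bulge (adjusted p = 0.00101 to 0.0103). Interferon response genes were mixed as well. Usp18 (3.68-fold, SE 0.29) and Ifit1 (3.14-fold, SE 0.24) were higher in bulge than in germ (adjusted p = 0.000331 to 0.000466). Mx1 (2.1-fold, SE 0.22) was higher in germ than in bulge (adjusted p = 0.00347).

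A hypothesis for bulge genes at intermediate levels in germ is that 1 fixed share of bulge cells lay in the germ samples, which may hold only if these genes imply the same share. Over 476 genes higher in bulge than in both others and at least 4-fold above epidermis, the implied share of bulge RNA had a median of 14.3%, with 10% of the genes below 1.86% and 90% below 37.9%, and 28 genes at 0 or less. This spread argues against 1 fixed share as the whole source. A share that differed between pools fits: 350 of these genes were lowest on germ replicate 3, and the median implied share was 20.2%, 16.5%, 6.39% and 15.7% on germ replicates 1 to 4, while 8 of 11 sebaceous gland genes were highest on germ replicate 3. Cd34, whose antigen the germ cells were sorted to lack, stood at 9.70, 9.92, 7.19 and 7.84 on germ replicates 1 to 4, also lowest on replicate 3. Lower expression of bulge genes by the germ cells of that pool would give the same. A share of bulge cells as a part of the source, and expression by germ cells, therefore both stay open.

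With the replicate number in the model, 155 of 15320 genes were called for it (1.01%), and 3 of 17 circadian clock genes (17.6%), Dbp, Per2 and Per3. Fisher's exact test, one-sided, gave p = 0.000622 for this share. Mean log2 deviations from the group means on replicates 1 to 4 were -1.30, 0.66, 0.48 and 0.16 for Dbp, -0.71, 0.99, 0.32 and -0.60 for Per2, and -0.95, 0.56, 0.45 and -0.06 for Per3. Collection of the pools at different times of day, which the labels do not give, is a candidate explanation found and tested on the same data.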
